A study of Mus musculus with 4 samples.

How the data were processed

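The data were 4 Affymetrix arrays hybridised with labelled cDNA from RNA of crypt cells of the adult mouse small intestine, sorted by flow cytometry. The mice carried an EGFP and CreERT2 reporter in the Lgr5 gene and a villin-CreERT2 driver, and received tamoxifen for 2 days before crypts were isolated. In the Zip7 KO mice both copies of Slc39a7, the gene of the zinc transporter ZIP7, were floxed; in the control mice 1 copy was floxed under the same drivers, so that the controls are expected to have lost 1 copy. Cells labelled Lgr5-Hi and cells labelled Lgr5-Med were taken from each genotype, which gives 4 groups of 1 array each. The sample titles give the second fraction as Lgr5-Mid and the source names as Lgr5-Med, and the latter is used here. The labels do not say how many animals contributed to an array, nor whether the fractions of 1 genotype came from the same mice.

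The deposited values are log2 values per probe set that the authors made with RMA, named in the submitters' processing notes. The log base, the software, its version, the probe set annotation and the arrays normalised together are not given in the sources used here. The values were taken as log2 because they lay between 3.08 and 14.6, with array medians from 6.34 to 6.45 and no missing value. All 4 columns of values were used and 0 were left out.

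Of 35557 probe sets, 21789 were paired with 1 gene symbol by the platform's annotation, 1621 with several symbols, and 12147 were not listed in it. Only the first kind was analysed. Of these, 21698 had an Entrez gene ID that matched the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols had to be updated. The build behind the arrays is not given in the sources used here, so that table served for names and gene order only. The level of a gene was that of its probe set with the highest mean over the 4 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. Most defensin probe sets name several genes, as does that of Cdkn1a, and Ccnb1 is not listed in the annotation, so these genes were not analysed here.

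A floor for expression was set on each array at percentile 95 of 1207 olfactory, vomeronasal and trace amine receptor genes, which the intestine should not express. The floors were 6.25 for the control array labelled Lgr5-Hi, 6.10 for the control array labelled Lgr5-Med, and 6.18 and 6.16 for the Zip7 KO arrays with these labels. The genes above them numbered 11734, 12099, 11731 and 11877 in the same order. A gene entered a comparison if it was above the floor on at least 1 of its 2 arrays. Where a named gene was at or below the floor on 1 of the 2 arrays, the floor took the place of that value, and the difference is given as at least that size. The counts and the list medians used the deposited values. The receptor genes themselves were left out of the counts.

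There were 4 comparisons, each of 1 array against 1 array. These were Zip7 KO minus control within each fraction label, and labelled Lgr5-Hi minus labelled Lgr5-Med within each genotype. With 1 array per group there is no spread between animals within a group, no comparison was tested, and the number of arrays limits the precision. An additive fit of genotype and fraction over the 4 arrays, which would take any difference between the genotype differences as noise, was not run. Genes were counted past a fixed size of 2-fold (1 on the log2 scale), and no p-value was computed for any gene. The overlap of 2 comparisons was set beside the number that independent lists would share. The difference between the genotype differences of the 2 fractions is given as a value and was not tested.

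The 29 gene lists covered ER chaperones and ER-associated degradation (targets of ATF6 and XBP1), PERK-ATF4-CHOP targets, cytosolic heat shock proteins, zinc transporters and metallothioneins, S phase and DNA replication, and G2/M and mitosis. Further lists held intestinal stem cell markers, Wnt target genes, the Notch pathway, p53 targets and apoptosis, and markers of Paneth, goblet, enteroendocrine and tuft cells and of enterocytes. Lists for other cells held lymphocyte and myeloid markers and stromal, endothelial and red blood cell markers. The remaining lists were interferon-stimulated genes, regenerative and fetal-like epithelial genes, NF-kB and inflammatory genes, immediate-early genes, NRF2 and oxidative stress genes, cholesterol synthesis, autophagy and lysosome, oxidative phosphorylation, cytosolic ribosomal proteins, antigen presentation (MHC class II), sex-linked genes and housekeeping genes. Members above the floor on at least 1 of the 4 arrays were used, so some were below it on both arrays of a comparison. A list's median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins, and called outside them below percentile 2.5 or above percentile 97.5. The interval of a median came from 2000 bootstrap draws of the list's members at a level of 95%. Percentile and interval describe the genes of these libraries, not animals.

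Named genes followed a rule. It took in each comparison the 10 largest differences in each direction among genes with a proper name, up to 4 members of each list in the direction of its median and up to 2 in the other, the genes 2-fold different in both fractions, and a fixed set that included Slc39a7, Lgr5, Olfm4, Ascl2, Smoc2, Hspa5, Ddit3, Mki67, Lyz1, Muc2, Chga and Epcam. The groups, comparisons, floor, thresholds, lists, naming rule and most of the other settings tried were chosen before the data were examined.

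The other settings chosen in advance were quantile normalisation of the 4 arrays, differences centred on the median, removal of a loess trend on the mean level (span 0.3), no floor, the upper part of genes by mean level, the mean of all probe sets of a gene, genes with a single probe set, thresholds of 1.5-fold and 3-fold, means in place of medians, and random lists matched in 10 bins or not matched. Counts without sex-linked genes, counts without the members of the interferon and immune lists, counts with values below the floor raised to it, and lists of members above the floor on 1 of the 2 arrays compared were added after the data were seen. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

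The procedure was tested on simulated data, in which every array was the control array labelled Lgr5-Hi plus independent noise, with 12049 genes counted. The noise SD of 0.171 per difference was that of the receptor genes between Zip7 KO and control under this label. Over all genes counted in that comparison the SD was 0.246. Differences were given only to genes more than 2 above the floor on the log2 scale. Of genes given a 3-fold difference 100% passed the 2-fold size, and of genes given a 1.5-fold difference 1% did. These shares follow largely from the noise SD. On the arrays, 1 of the 1207 receptor genes was at least 2-fold higher in Zip7 KO than in control under the label Lgr5-Hi, at 1.06. Between the control arrays 1 was so, at 1.05. In the simulation a list shifted by 0.3 was found at 0.35, at percentile 100, and 2 of 57 unshifted list medians fell outside the random lists. As the simulated noise was independent between genes, this does not cover lists whose members vary together.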

Results

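The study measured gene expression in sorted crypt cells of the mouse small intestine in which Slc39a7 (Zip7), a transporter that moves zinc out of the endoplasmic reticulum (ER) and Golgi, was deleted in the epithelium, and its title concerns proliferation and stem cell maintenance. There were 4 arrays, 1 for each combination of genotype (control or Zip7 KO) and fraction label (Lgr5-Hi or Lgr5-Med), with no replicates. The arrays correlated across probe sets with r from 0.983 to 0.990, where probe sets are not independent replicates.

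The deleted gene itself was measured on every array. Slc39a7 stood at 8.92 in the control array labelled Lgr5-Hi and 9.02 in the Zip7 KO array with that label, and at 8.61 and 8.22 in the control and Zip7 KO arrays labelled Lgr5-Med. The Zip7 KO values thus differed from the controls by 0.10 and -0.39 on the log2 scale. Where the probes lie relative to the floxed exons is not given in the sources used here. Probes outside the deleted part would still detect a transcript, whereas probes inside it should have lost signal. These values therefore neither show the deletion nor exclude it.

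Lgr5, the receptor whose reporter was used for sorting, ran against the fraction labels. Its level was 7.79 in the control array labelled Lgr5-Hi and 10.97 in the control array labelled Lgr5-Med, and 7.93 and 11.24 in the corresponding Zip7 KO arrays. The stem cell transcription factor Ascl2 (7.65 against 9.54 in controls), the stem cell marker Smoc2 (9.61 against 10.70) and the crypt base marker Olfm4 (12.88 against 13.53) were likewise lower in the array labelled Lgr5-Hi. The labels are kept as given and no array was regrouped, so every direction between fractions below is that of the labels. The genotype comparisons pair arrays with the same fraction label, and an exchange of the labels in both genotypes would rename these comparisons without altering their values.

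The sex of the mice was confounded with genotype. Xist, the RNA of the inactive X chromosome, was at 11.64 and 11.84 in the control arrays and at 5.59 and 5.43, below the floor, in the Zip7 KO arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d lay below the floor in the control arrays and were higher in the Zip7 KO arrays by at least 1.87, 1.60 and 1.46 in the arrays labelled Lgr5-Hi and by at least 2.01, 1.97 and 1.52 in those labelled Lgr5-Med. The control arrays therefore had the expression of female cells and the Zip7 KO arrays that of male cells. The median of the 4 sex-linked genes, 2.87 and 2.90, is one of opposite signs and has no meaning of its own.

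**Figure D1:**
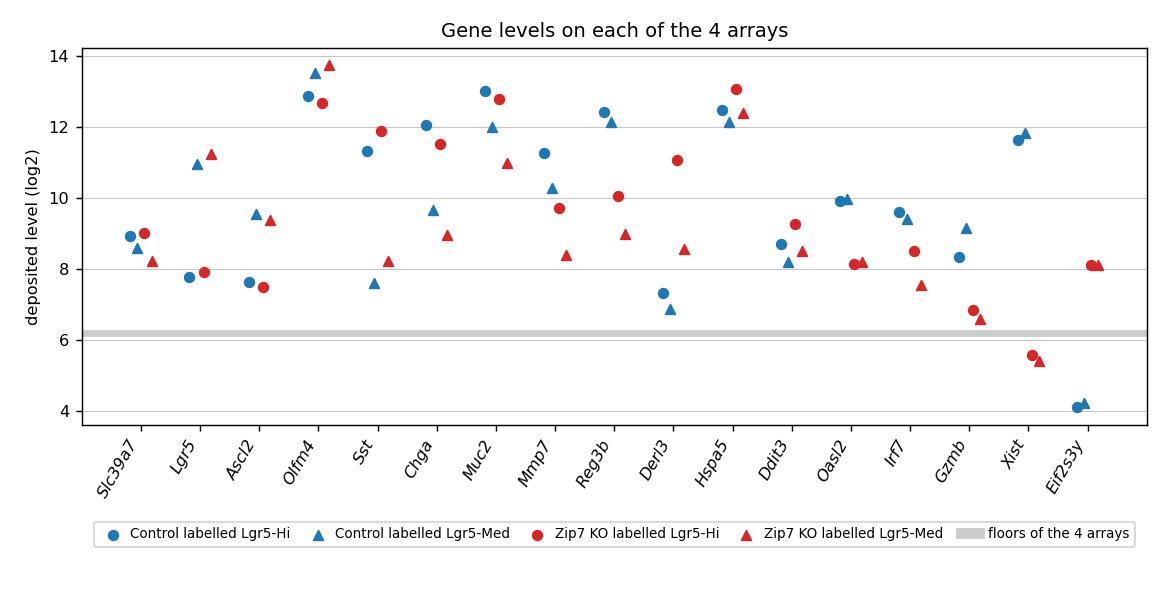
Deposited level (log2) of 17 genes on each of the 4 arrays, 1 point per array, with controls in blue, Zip7 KO in red, circles for the label Lgr5-Hi and triangles for Lgr5-Med, and the expression floors as a grey band. Lgr5 lies near 7.79 and 7.93 under the label Lgr5-Hi and near 10.97 and 11.24 under the label Lgr5-Med, and Xist separates the genotypes.

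The first comparison asked how Zip7 KO and control cells labelled Lgr5-Hi differed. Genes of the unfolded protein response, by which cells adjust to misfolded protein in the ER, were higher in the Zip7 KO array. Derl3, a component of ER-associated degradation, was higher by 3.73 (13.2-fold), the ER stress genes Creld2 and Sdf2l1 by 1.61 and 1.15, the protein disulfide isomerase Pdia4 by 1.12, and Hspa5 (BiP), the main ER chaperone, by 0.61, from 12.48 to 13.09. All 34 members above the floor of the list of ER chaperones and ER-associated degradation were higher, 5 of them at least 2-fold. The median was 0.47 (bootstrap interval 0.35 to 0.78), above the random lists at percentile 100. Xbp1 and Atf4, transcription factors of this response that are also controlled by splicing and translation, were higher by 0.13 and 0.28.

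Targets of the PERK-ATF4-CHOP arm of this response were higher as well. Chac1, which degrades glutathione, was higher by 1.15, the pseudokinase Trib3 by 1.03, the transcription factor Atf5 by 0.87 and Ddit3, which encodes CHOP itself, by 0.56. The cystine transporter Slc7a11 was higher by at least 0.99, with its control value below the floor. Of the 35 targets above the floor 31 were higher, with a median of 0.29 (0.27 to 0.51) at percentile 100. Phgdh, an enzyme of serine synthesis, was lower by -0.32. The cholesterol synthesis list, with a median of 0.20, and the cytosolic heat shock proteins, with a median of 0.19, stood at percentiles 99.9 and 99.3.

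Genes of the interferon response were lower in the same Zip7 KO array. The antiviral genes Oas2 and Oasl2 differed by -1.94 and -1.76, Ifit1, below the floor in Zip7 KO, by -1.55 or lower, the nucleic acid sensor Zbp1 by -1.42, and Irf7, a transcription factor of the interferon response, by -1.12. All 22 interferon-stimulated genes of the list were lower, 9 of them at least 2-fold and 21 of them above the floor on either of these arrays, with a median of -0.95 (-1.27 to -0.60) at percentile 0. Markers of lymphocytes were lower too, with the granzymes Gzmb and Gzma at -1.47 and -1.25, the T cell antigen Cd7 at -1.23 and the chemokine Ccl5 at -1.08. All 19 lymphocyte and myeloid markers used were lower, 17 of them above the floor on either of these arrays, with a median of -0.53 at percentile 0. The antigen presentation (MHC class II) list had a median of -0.36, also at percentile 0, with its regulator Ciita at -0.60. The sex of the mice differed between these arrays as given above.

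Markers of Paneth, goblet and enteroendocrine cells were lower as lists. Among the Paneth cell markers the protease Mmp7, which processes defensins, was at -1.55, the lectin Reg3g at -1.29 and the phospholipase Pla2g2a at -0.94. Lysozyme Lyz1 was at -0.11. The antimicrobial lectin Reg3b, at -2.36, belongs to the NF-kB and inflammatory list and is not among these markers. Of the 14 Paneth markers above the floor 13 were lower, with a median of -0.61 (-0.88 to -0.24) at percentile 0, and the stress-induced gene Nupr1 was higher by 0.68. Most defensins lack a probe set of their own and are not among the 14. The goblet cell markers had a median of -0.16 and the enteroendocrine markers one of -0.25, both at percentile 0, with the mucin Muc2 at -0.24, the granule protein Chga at -0.53 and Insm1, a transcription factor of endocrine cells, at -0.63. Of the 19 goblet markers 5 were higher, among them Clca1 at 0.45 and Agr2 at 0.27, and of the 25 enteroendocrine markers 6 were, among them the hormone genes Sst at 0.55 and Gip at 0.25. Atoh1, the transcription factor that starts the secretory lineage, was at -0.56, and the Notch pathway list that holds it had a median of -0.20 at percentile 0.

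Genes of stem cells and of the cell cycle differed less. The stem cell markers had a median of -0.09 (-0.14 to 0.01) at percentile 0.03, with 12 of 32 members higher. On one side were the RNA-binding protein Msi1 at -0.44 and the Wnt target Axin2 at -0.36. On the other were the urea transporter Slc14a1 at 0.58 and Lgr5 at 0.14. The Wnt target genes had a median of -0.10 (-0.30 to 0.03) at percentile 0.47, but within random lists that were not matched on level. Both bootstrap intervals included 0. Of the 15 Wnt target genes 11 are also stem cell markers, and the other 4 had a median of 0.03, with 1 of them lower. The S phase and DNA replication list had a median of -0.14 (-0.088 as a mean) at percentile 0, with 25 of 34 members lower, among them the DNA polymerase subunit Pold1 at -0.45, whereas the cyclin Ccne2 was at 0.40. The G2/M and mitosis list had a median of -0.10 (-0.16 with the loess trend on mean level removed) at percentile 0.02, with the proliferation marker Mki67 at -0.17. The immediate-early genes had a median of -0.10 at percentile 0.01. The p53 targets and apoptosis list, with a median of 0.12, the zinc transporters and metallothioneins, with 0.11, and the NRF2 and oxidative stress genes, with 0.13, lay within the random lists at percentiles 97.1, 95.4 and 96.7, but above random lists not matched on level, at 97.9, 98.4 and 98.7. Without the p53 target below the floor on both arrays that list stood at 99.4. The zinc exporter gene Slc30a1 was at -0.40, and the metallothioneins Mt1 and Mt2, which bind zinc, at 0.13 and 0.27.

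The remaining lists lay within the random lists. These were tuft cell markers (median -0.07, percentile 6.89), enterocyte markers (0.03, 12.3), stromal, endothelial and red blood cell markers (-0.18, 3.54, but 0.83 against random lists not matched on level), NF-kB and inflammatory genes (0.06, 75.4), and regenerative and fetal-like genes (0.01, 45.3). Autophagy and lysosome (0.05, 39.7), oxidative phosphorylation (0.01, 2.71), ribosomal proteins (0.05, 33.0) and housekeeping genes (0.11, 81.5) lay there too. For enterocyte, regenerative, autophagy, oxidative phosphorylation and ribosomal lists the sign turned under at least 1 scaling alternative. The epithelial genes Epcam and Vil1 differed by 0.05 and 0.02. In all, 30 of 11988 genes were at least 2-fold higher and 28 at least 2-fold lower, or 14 lower without the members of the interferon and immune lists. These 14 still held interferon-induced genes that are not in the lists, among them Rtp4, Trim30a, Ddx60 and Herc6. Without sex-linked genes 26 were higher and 27 lower. With 1 array per genotype and fraction label no difference was tested, and the percentiles are a description of these libraries.

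The second comparison asked the same of the arrays labelled Lgr5-Med, where 8 of 12243 genes were at least 2-fold higher and 76 at least 2-fold lower. The 8 included the Y-linked genes Eif2s3y, Uty, Kdm5d and Srsy. The others were Nox1, a superoxide-producing NADPH oxidase (1.97), Derl3 (1.68), the semaphorin Sema7a (1.31) and Hs3st1, a heparan sulfate sulfotransferase (1.05). Without the sex-linked genes the count of higher genes was 4.

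Interferon-stimulated genes were again lower. Usp18, which removes the ubiquitin-like ISG15, was at -1.94 or lower, its Zip7 KO value being below the floor, Irf7 at -1.84, Ifit1 at -1.81 and Zbp1 at -1.80. All 22 members above the floor were lower, 12 of them at least 2-fold, with a median of -1.09 (-1.34 to -0.77) at percentile 0. The lymphocyte and myeloid markers were lower in 19 of 19 cases with a median of -0.63, Gzmb standing at -2.55 and the natural killer cell gene Nkg7 at -1.55. The MHC class II list had a median of -0.44. Both lay near the bottom of the random lists, at percentiles 0 and 0.01.

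The Paneth and goblet cell lists were lower in this fraction too. Reg3g was at -2.03, Mmp7 at -1.89, the colipase Clps at -1.55 and the intelectin Itln1 at -1.54. Of the 14 Paneth markers 13 were lower, with a median of -1.09 (-1.50 to -0.56) at percentile 0. Reg3b, of the NF-kB and inflammatory list, was at -3.16. The goblet list had a median of -0.39 at percentile 0, with Spink4, a secreted protease inhibitor, at -1.34 and Muc2 at -1.03. The enteroendocrine list had a median of -0.10, within the random lists at percentile 5.87 but below them at 2.35 after quantile normalisation. Of its 25 members 5 were below the floor on both arrays, and 9 were higher, among them Sst at 0.62 and Ghrl at 0.36, while the proglucagon gene Gcg was at -1.43. The tuft cell list had a median of 0.17 (-0.09 to 0.30) at percentile 100, with 10 of 16 members higher, among them its marker Dclk1 at 0.36.

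Absorptive cell genes were lower under the label Lgr5-Med. All 30 enterocyte markers were lower, with a median of -0.38 (-0.51 to -0.30) at percentile 0. Slc51b and Slc51a, which form the basolateral bile acid exporter, were at -0.93 and -0.87, the brush border peptidase Enpep at -0.83 and the keratin Krt20, a marker of mature enterocytes, at -0.73. The iron exporter Slc40a1, below the floor in Zip7 KO, was at -1.78 or lower, the fatty acid binding protein Fabp1 at -0.51 and Vil1 at -0.30, while Epcam was at 0.07.

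The ER genes differed less under this label. The ER chaperone list had a median of 0.08 (-0.01 to 0.18) at percentile 99.0 and a mean of 0.14, with 22 of 34 members higher, Derl3 at 1.68, Sdf2l1 at 0.59, Creld2 at 0.51 and Hspa5 at 0.25, against Sec24d, a gene of ER export vesicles, at -0.33. The PERK-ATF4-CHOP targets had a median of 0.08 at percentile 99.8 (0.13 after quantile normalisation), with Ddit3 at 0.30, Trib3 at 0.31 and Atf4 at 0.03. The cytosolic heat shock proteins had a median of 0.14 at percentile 99.5.

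Genes of DNA replication and of mitosis differed in opposite directions. The S phase and DNA replication list had a median of 0.10 at percentile 99.9, with the chromatin remodeller Hells at 0.76 and Ccne2 at 0.50, and with Pold1 at -0.54. The G2/M and mitosis list had a median of -0.18 at percentile 0.01, with 31 of 34 members lower, among them the kinesin Kif2c at -0.58, while Mki67 was at 0.03. The stem cell markers had 16 members on either side of 0 and a median of -0.0020 at percentile 68.4, with the stem cell gene Gkn3 at 0.61 and Lgr5 at 0.27. The NF-kB and inflammatory genes, with a median of -0.22, the immediate-early genes, with -0.20, and the regenerative genes, with -0.15, lay below the random lists at percentiles 0.04, 0.01 and 1.24, the last of these within them after quantile normalisation. The bootstrap interval of the regenerative genes (-0.23 to 0.07) included 0.

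The other lists lay within the random lists. They were Wnt targets (median -0.03, percentile 47.5), the Notch pathway (-0.04, 41.2), zinc transporters and metallothioneins (-0.04, 44.5), p53 targets (0.02, 83.4), cholesterol synthesis (0.01, 74.5) and NRF2 genes (0.00057, 56.5). Autophagy (-0.03, 49.5), oxidative phosphorylation (-0.02, 19.3), ribosomal proteins (0.02, 54.9), stromal, endothelial and red blood cell markers (0.04, 76.4) and housekeeping genes (0.08, 89.9) were the rest. The signs of the stem cell, zinc, NRF2, autophagy, oxidative phosphorylation and ribosomal medians turned under at least 1 scaling alternative. Slc30a1 was at -0.77 and the intestinal zinc importer gene Slc39a4 at -0.62.

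**Figure D2:**
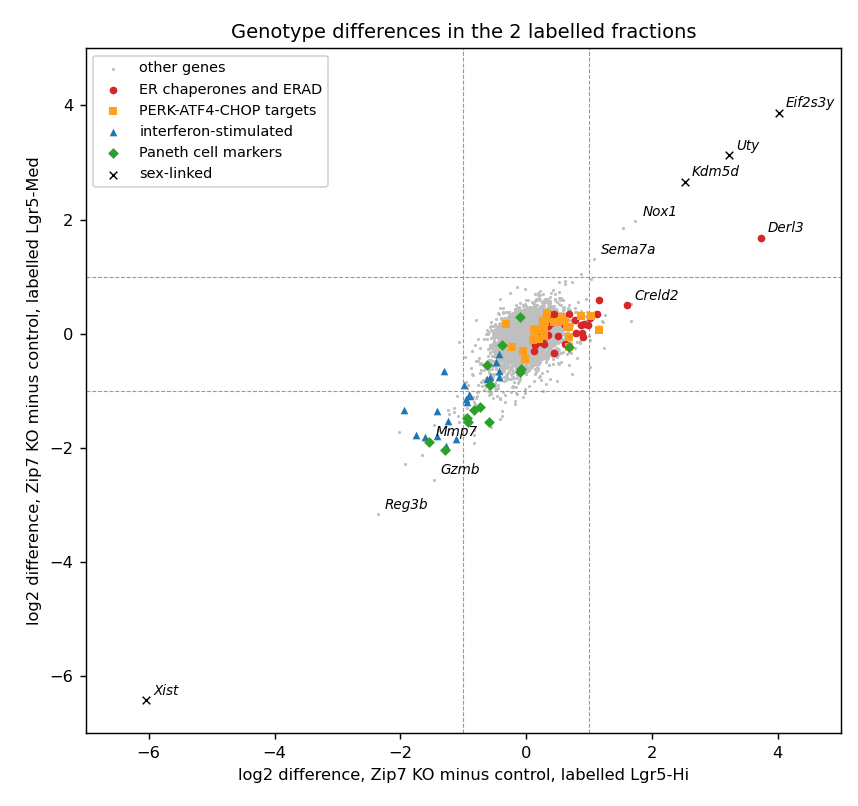
Log2 difference, Zip7 KO minus control, of each gene above the floor in both fractions, with the arrays labelled Lgr5-Hi on the horizontal axis and those labelled Lgr5-Med on the vertical axis; dashed lines mark 2-fold. The ER chaperones and PERK-ATF4-CHOP targets spread to the right, with Derl3 at 3.73 and 1.68, and the interferon-stimulated genes lie below 0 on both axes.

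The 2 genotype comparisons shared genes. Of 11827 genes counted in both, 26 were at least 2-fold higher under the label Lgr5-Hi and 8 under Lgr5-Med, and 7 were so in both, where independent lists would share 0.0176. These were Eif2s3y, Uty, Kdm5d, Srsy, Nox1, Derl3 and Sema7a. At least 2-fold lower were 28 and 73, and 26 in both, where independent lists would share 0.173. Beside Xist they included Reg3b, Mmp7, Gzmb, the interferon-induced genes Rtp4, Oasl2, Ifit1 and Trim30a, the nuclear body protein Sp100 and Zbp1. Whether the fractions of a genotype shared mice is not in the labels, so these comparisons are not known to be independent.

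For each gene and list the genotype difference under the label Lgr5-Hi minus that under Lgr5-Med was taken, and this difference was not tested. For the ER chaperone list it had a median of 0.42 (0.34 to 0.64) at percentile 100, above 0 in 34 of 34 members, with Derl3 at 2.04. For the PERK-ATF4-CHOP targets it was 0.25 at percentile 100. The enterocyte markers, at 0.48 and above 0 in 30 of 30, and the Paneth and goblet markers, at 0.53 and 0.36, were also at percentile 100. The zinc, interferon and NF-kB lists also lay above the random lists, with medians of 0.21, 0.18 and 0.31. Below them were S phase genes (-0.20) and stem cell markers (-0.13), both at percentile 0, and the Wnt (-0.12), heat shock (-0.08), Notch (-0.08), tuft (-0.11) and enteroendocrine (-0.07) lists. The bootstrap intervals of some of these lists included 0. They were the Wnt (-0.25 to 0.01), heat shock (-0.17 to 0.03), Notch (-0.29 to 0.05) and enteroendocrine (-0.25 to 0.04) lists. That of the goblet list (-0.04 to 0.52) included 0 as well.

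The other comparisons set the fraction labels against each other within a genotype. In controls, hormone genes of enteroendocrine cells had the largest positive differences of labelled Lgr5-Hi minus labelled Lgr5-Med: somatostatin (Sst) 3.74, Gip 3.49, cholecystokinin (Cck) 2.98, the tachykinin gene Tac1 2.97, ghrelin (Ghrl) 2.82 and Tph1, the enzyme of serotonin synthesis, 2.81. All 25 enteroendocrine markers were higher, 17 of them at least 2-fold and 24 above the floor on either array, with a median of 1.61 (0.95 to 2.40) at percentile 100. The goblet and Paneth markers had medians of 0.93 and 0.81 and the tuft markers one of 0.40, each at percentile 100, with Muc2 at 1.02, Itln1 at 1.42 and Dclk1 at 1.01. Vim, listed among stromal genes, was at 2.10, while the stromal, endothelial and red blood cell list had a median of 0.11 at percentile 84.4.

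The stem cell markers stood on the other side. All 32 were lower in the control array labelled Lgr5-Hi, 16 of them at least 2-fold and 31 above the floor on either array, with a median of -0.97 (-1.23 to -0.74) at percentile 0. Lgr5 was at -3.18, Slc14a1 at -2.36, Cyp2e1 at -2.35, Gkn3 at -2.13, Ascl2 at -1.89 and the IGF binding protein Igfbp4 at -1.77. All 15 Wnt target genes above the floor were lower, with a median of -0.92 at percentile 0, Axin2 being at -1.44 and Myc at -1.27. Of these 15 genes 11 are also stem cell markers, and the other 4 had a median of -0.41. The S phase list (-0.30, with 29 of 34 members lower) and ribosomal proteins (-0.21, with 33 of 34) were at percentile 0, and the G2/M list at -0.17 was at 0.87. The lymphocyte and myeloid markers had a median of -0.31 and the MHC class II list one of -0.57, both at percentile 0.

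Of the other lists in controls, the ER chaperones (0.39, all 34 higher), the PERK-ATF4-CHOP targets (0.18), cholesterol synthesis (0.26) and the immediate-early genes (0.18) were at percentile 100. Regenerative genes (0.17) and NRF2 genes (0.12) were both at 99.7, the former within the random lists at 97.4 without its member below the floor on both arrays, zinc transporters (0.06) at 98.9 and oxidative phosphorylation (0.05) at 98.1. Both of the latter lay within random lists not matched on level, and oxidative phosphorylation also after quantile normalisation or removal of the loess trend. Enterocyte markers were at -0.15 and percentile 0.75. The bootstrap intervals of the enterocyte (-0.24 to 0.01), regenerative (-0.02 to 0.45) and oxidative phosphorylation (-0.01 to 0.10) lists included 0. Interferon-stimulated genes (-0.0040, percentile 78.3), the Notch pathway (-0.00016, 74.1), autophagy (-0.02, 79.1), heat shock proteins (-0.05, 39.6), p53 targets (-0.09, 19.1), NF-kB genes (-0.08, 32.0) and housekeeping genes (-0.03, 45.1) lay within the random lists. All of these but the p53 targets turned sign under at least 1 scaling alternative. Sex-linked genes were at -0.17 and percentile 7.79, but 3 of the 4 were below the floor on both arrays.

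In Zip7 KO mice enteroendocrine and stem cell genes stood apart in the same directions. Sst was at 3.67, Cck at 3.48, Gip at 3.47 and Gcg at 3.13, and all 25 enteroendocrine markers were higher under the label Lgr5-Hi, with a median of 1.60 at percentile 100. All 32 stem cell markers were lower, 21 of them at least 2-fold, with a median of -1.11 (-1.42 to -0.98) at percentile 0, Lgr5 at -3.31, Gkn3 at -2.39, Ascl2 at -1.89 and Msi1 at -1.69. All 15 Wnt targets above the floor were lower with a median of -1.11 at percentile 0, and the 4 that are not stem cell markers had a median of -0.42. The Paneth, goblet and tuft markers had medians of 1.24, 1.22 and 0.34 at percentile 100. The ER chaperones had a median of 0.88 (0.70 to 1.11), with 34 of 34 members higher, 14 of them at least 2-fold, Creld2 at 1.54 and Syvn1, the ubiquitin ligase of ER-associated degradation, at 1.33. The PERK-ATF4-CHOP targets had a median of 0.43, also at percentile 100, with Chac1 at 1.57. Enterocyte markers, at -0.15 in controls, had a median of 0.31 at percentile 100 here, a difference that was not tested, with intestinal alkaline phosphatase (Alpi) at 1.16.

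Further lists in Zip7 KO mice lay above the random lists, namely cholesterol synthesis (median 0.35, percentile 100), zinc transporters (0.24, 100), NF-kB genes (0.28, 99.9), immediate-early genes (0.26, 99.8), NRF2 genes (0.24, 99.8) and regenerative genes (0.21, 99.3). The bootstrap intervals of the zinc transporters (-0.01 to 0.43) and the regenerative genes (-0.07 to 0.56) included 0. Lower than the random lists were S phase genes (-0.46, 0), G2/M genes (-0.14, 0.68), the Notch pathway (-0.22, 0.14), ribosomal proteins (-0.16, 0.04) and the MHC class II list (-0.48, 0.02). Within them were interferon-stimulated genes (0.13, 96.6, but 98.5 without the 2 members below the floor on both arrays), lymphocyte and myeloid markers (-0.14, 3.01, but 1.73 after quantile normalisation and 0.98 with the loess trend removed), heat shock proteins (-0.07, 18.1), p53 targets (0.03, 63.7) and autophagy (0.09, 84.6). Oxidative phosphorylation (0.10, 91.1), stromal, endothelial and red blood cell markers (-0.05, 35.3), housekeeping genes (-0.10, 12.5) and sex-linked genes (0.05, 70.8, with 1 of the 4 below the floor on both arrays) were also within them.

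The counts between fractions were 82 genes at least 2-fold higher and 64 lower of 12248 in controls, and 227 higher and 91 lower of 12114 in Zip7 KO mice. In controls 56.2% of these genes were higher, and 66.7% (102 higher and 51 lower) after removal of the loess trend on mean level. At 1.5-fold this balance turned in controls, with 282 higher and 385 lower. Of 11958 genes counted in both genotypes, 66 were at least 2-fold higher in both, where independent lists would share 1.48, and 52 were lower in both, where they would share 0.482. No gene was 2-fold higher in one genotype and 2-fold lower in the other. Over all 4 comparisons 73 of 116 list medians lay outside the random lists, where 5.8 would by chance if genes were independent, which members of a pathway are not. The 116 medians are not separate chances either, as some lists share members and the 4 comparisons share arrays. As the stem cell markers ran against the labels, the fraction that each of these directions describes rests on the labels.

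**Figure D3:**
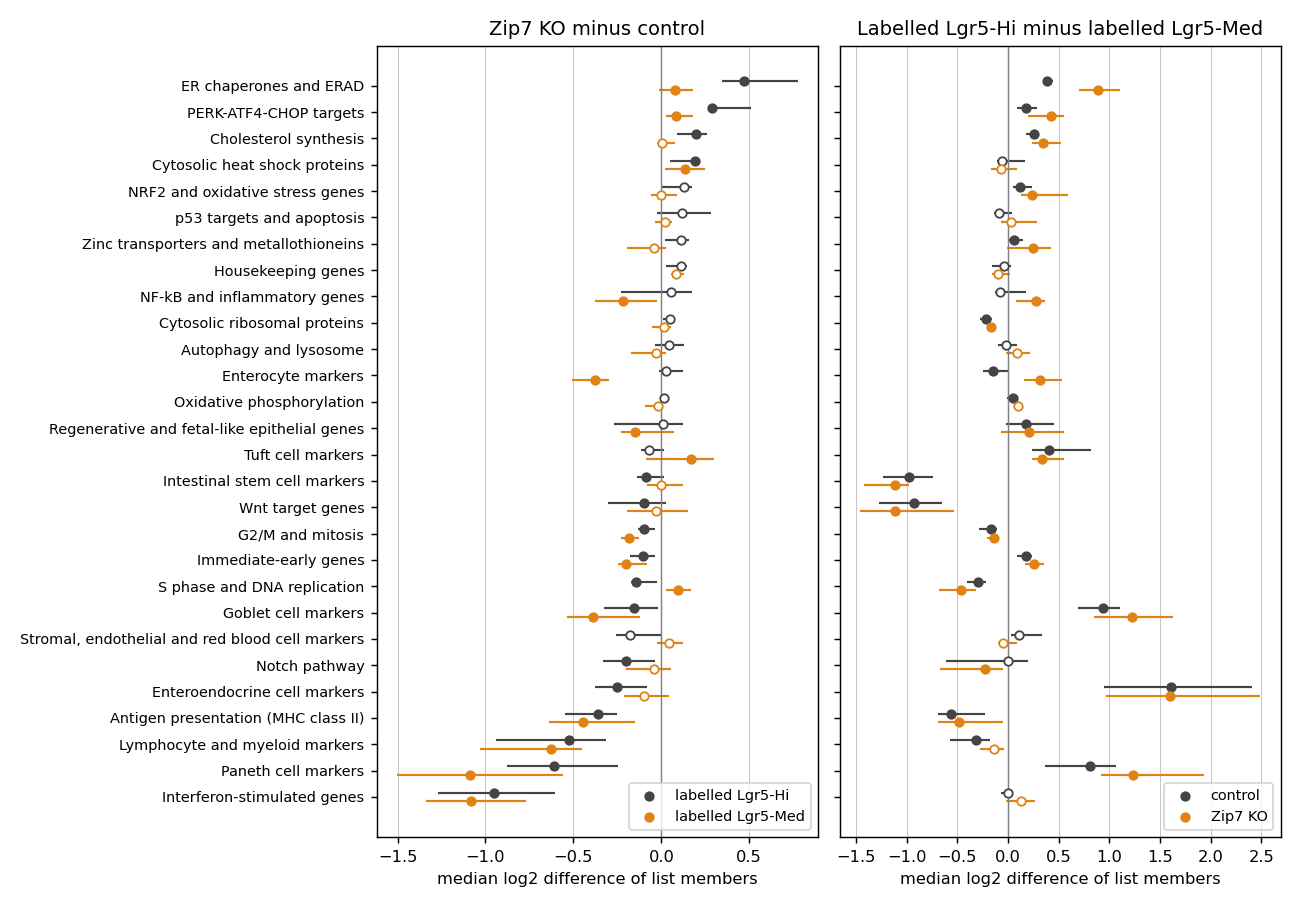
Median log2 difference of the members of 28 gene lists, with bootstrap intervals over members as lines, for Zip7 KO minus control on the left and labelled Lgr5-Hi minus labelled Lgr5-Med on the right; open points lie within the random lists. Interferon-stimulated genes lie at -0.95 and -1.09 on the left, and stem cell markers lie at -0.97 and -1.11 on the right.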

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

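All tests that weigh an explanation here were chosen only after the result was seen, and with 1 array per group none of the differences between groups was tested.

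Probe sets that name several genes entered no comparison, and 62 of them were at least 2-fold higher and 13 lower in the Zip7 KO array labelled Lgr5-Hi than in its control. Under the label Lgr5-Med the numbers were 66 and 7. Of the higher ones 62 and 63 name a Y-linked gene, so they go with the sex of the mice. The lower ones under both labels included probe sets of Oas1a and Oas1g, of Irgm2 and Igtp, of Tgtp1 and Tgtp2, and of T cell receptor gamma segments. Under the label Lgr5-Hi they also included probe sets of the Btbd35f gene family. Among probe sets without a gene in the annotation 221 were higher and 43 lower of 5526 above the floor under the label Lgr5-Hi, and 250 were higher and 32 lower of 5579 under Lgr5-Med.

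The median of the S phase and DNA replication list was below 0 between genotypes under the label Lgr5-Hi (-0.14) and above 0 under Lgr5-Med (0.10). The enterocyte markers, labelled Lgr5-Hi minus labelled Lgr5-Med, had a median of -0.15 (-0.24 to 0.01) in controls and 0.31 in Zip7 KO mice. Neither difference was tested.

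The ER chaperone list was higher in the Zip7 KO array labelled Lgr5-Hi, with a median of 0.47. With the loess trend on mean level removed the median was 0.39 (bootstrap SD 0.12) at percentile 100, which argues against a brightness-dependent normalisation trend as the whole cause. The 58 Paneth, goblet and enteroendocrine markers above the floor, whose cells are rich in ER, had a median of -0.26 (bootstrap SD 0.05). Of the 14 Paneth markers 1 was higher, of the 19 goblet markers 5 and of the 25 enteroendocrine markers 6. The median argues against more secretory cells in the Zip7 KO sort only if each cell kept its marker levels, which was not measured. The sex of the mice cannot be told apart from the loss of Zip7, since 0 of the genotypes hold arrays of both sexes. The loss of Zip7, sex and a difference between single animals or sorts therefore stay open, and no biological explanation was tested on its own.

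Stem cell markers were lower in the arrays labelled Lgr5-Hi, with medians of -0.97 in controls and -1.11 in Zip7 KO mice. Without Lgr5 the other 31 markers had medians of -0.93 and -1.11, so the pattern was not one of the Lgr5 transcript alone. As all 32 markers were lower in both genotypes, leaving out 1 could not turn the median. Whether the reporter allele lowers the Lgr5 transcript itself is not decided by this. The G2/M list stood at -0.17 and -0.14 and the S phase list at -0.30 and -0.46, both above the stem cell list. Dilution of an Lgr5-Hi sort by non-dividing differentiated cells would lower these lists alike only if undiluted fractions had equal levels of them. That was not measured, so the lists cannot decide on such dilution. In controls the enteroendocrine, goblet, Paneth and tuft markers were higher under the label Lgr5-Hi, at 1.61, 0.93, 0.81 and 0.40. Enterocyte markers were at -0.15 there. Dilution by non-dividing cells stays open, as does dilution by dividing cells. An exchange of the fraction labels and a sorting gate that differed from the label, in both genotypes, were not tested and stay open.

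Interferon-stimulated genes were lower in both Zip7 KO arrays, and so were lymphocyte and myeloid markers. Between the controls the lymphocyte list stood at -0.31, from which the ratio of the lists between genotypes (1.76) predicts an interferon median of -0.55, but the observed median was -0.0040. The gap was 0.54 (bootstrap SD 0.22, interval 0.27 to 1.13), with a spread over genes and not over sorts or animals. It would argue against fewer lymphocytes in the Zip7 KO sorts only if other cells of both control fractions had equal interferon signals. That was not measured, so the gap cannot decide, and fewer lymphocytes stay open. Moreover, 3 of the 19 lymphocyte list genes (Cd74, H2-Aa and H2-Ab1) are also in the MHC class II list and epithelial cells can express them. The sex of the mice cannot be told apart from the loss of Zip7, as 0 of the genotypes hold both sexes. A lower interferon signal from lymphocytes and the loss of Zip7 in the epithelium were not tested and stay open.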

How the results depend on the processing

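The 4 alternatives that leave out sex-linked genes or the interferon and immune lists, raise values below the floor to it, or keep list members above the floor on 1 of the 2 arrays were chosen after the data were seen; the others were planned. With 1 array per group no replicate could be left out, and signal over background limits dim genes, whose differences against the floor are bounds. Of the counts of genes, 83 values under the alternatives stayed within 1.5 times the value given and 23 did not. Of the list medians 921 stayed within their bootstrap SD and 121 did not, apart from 2 that lay outside the random lists and turned sign. Of those within the random lists 44 turned sign. Of the percentiles 564 kept their side of the random lists and 16 did not. These concerned enteroendocrine, regenerative, oxidative phosphorylation and lymphocyte lists under scaling, and zinc, Wnt, p53, stromal, NRF2 and oxidative phosphorylation lists against random lists not matched on level, and p53, interferon and regenerative lists without members below the floor on both arrays. Of the values of named genes 5704 stayed within the spread of the receptor genes and 8 did not, all of these under the mean of all probe sets, and 714 of 714 differences of differences stayed.

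The size of the counts followed the threshold, as its construction requires. At 1.5-fold, 130 genes were higher and 111 lower in Zip7 KO under the label Lgr5-Hi, 52 and 257 under Lgr5-Med, and 15 and 83 in both. Between fractions they were 282 and 385 in controls, where 82 were higher and 64 lower at 2-fold, and 715 and 431 in Zip7 KO. Why the balance in controls turned was not tested. At 3-fold, 10 were higher and 8 lower under Lgr5-Hi, 20 lower under Lgr5-Med and 7 lower in both, and between fractions 24 and 8 in controls and 52 and 14 in Zip7 KO. Among the upper part of genes by mean level, where fewer genes are counted, the higher genes in Zip7 KO numbered 18, 3 and, in both, 3. Without sex-linked genes 4 genes were higher under Lgr5-Med, and without the interferon and immune lists 14 were lower under Lgr5-Hi. Interferon-induced genes outside these lists remained among the 14. With values below the floor raised to it, 26 were higher and 25 lower under Lgr5-Hi, and 7 and 71 under Lgr5-Med.

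Some list medians shifted with scaling, and the cause was not tested. With quantile normalisation the PERK-ATF4-CHOP targets were at 0.23 and 0.13 in Zip7 KO minus control under Lgr5-Hi and Lgr5-Med, the G2/M list at -0.16 and -0.14, and the S phase list at -0.20 under Lgr5-Hi. With the loess trend removed the same were at 0.22, 0.12, -0.16, -0.15 and -0.20. With differences centred on the median the G2/M list was at -0.12 under Lgr5-Hi. With no floor the interferon list was at -0.86 under Lgr5-Med. Among the upper part of genes the enteroendocrine markers between fractions were at 2.12 in controls and 2.03 in Zip7 KO. There the sex-linked list turned to -6.04 and -6.41 on the deposited values, as Xist alone was left in it. Against the floor Xist was at -5.46 or lower under Lgr5-Hi and at -5.68 or lower under Lgr5-Med. Means in place of medians gave 0.66 and 0.14 for the ER chaperones, 0.40 for PERK-ATF4-CHOP targets and -0.088 for S phase, both under Lgr5-Hi, and -1.11 for stem cell markers between fractions in controls.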

Other observations

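The single test of this part, on the neighbours of Slc39a7, was chosen after values of some of these genes had been seen, and the genes named here were chosen after their values were seen.

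Some single genes outside the lists were higher in Zip7 KO under the label Lgr5-Hi, and no list that would join them was fixed or tested. The cytochrome P450 gene Cyp2c68, below the floor in the control, was higher by at least 1.06, the aldo-keto reductase Akr1c19 by 1.26, the sulfotransferase Sult6b2 by 1.24, and the peroxisomal oxidase Acox2 by 1.15. Under the label Lgr5-Med Cyp2c68 was below the floor on both arrays, and the others differed by 0.33, -0.24 and 0.13. The glutathione transferase Gsta4 of the NRF2 list was at 1.22 and 0.20. The difference between the fractions was not tested.

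Other single genes outside the lists were lower in Zip7 KO, again without a list or a test, and the differences between fractions were not tested. The ileal bile acid binding protein Fabp6 was at -0.83 under Lgr5-Hi and -1.77 under Lgr5-Med, Slc5a4a at -0.83 and -1.68, the carbonic anhydrase Car4 at -0.41 and -1.50, and the vitamin B12 receptor Cubn at -0.87 and -1.33. The sodium-proton exchanger Slc9a3 was at -0.17 and -1.18 and the calcium binding protein S100g at -0.42 and -1.13. Below the floor in Zip7 KO, the interferon-induced gene Ddx60 was at -0.95 and -1.19 or lower and Herc6 at -0.86 and -1.22 or lower. Oas3 was at -1.15, and at -1.26 or lower under Lgr5-Med, where it was below the floor in Zip7 KO, and Rnf213 at -1.11 and -1.09. Of X-linked genes with a Y-linked partner, Eif2s3x was at -0.30 and -0.36, Kdm6a at -0.28 and -0.44 and Ddx3x at 0.08 and -0.0048.

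A chromosome segment that travels with a floxed allele could differ in strain origin between the genotypes, which could make the neighbours of Slc39a7, among them MHC genes, differ more than other genes. The median absolute genotype difference of the 100 nearest genes above the floor was 0.11 against 0.10 over all 12391 windows of neighbouring genes. It stood at percentile 73.4 of these windows, not above percentile 95, so the segment as a whole did not stand out. A median over 100 genes would miss a haplotype that alters few of them. The controls also carry 1 floxed copy, so the genotypes would differ by 1 copy of the segment only. This median therefore cannot decide on a flanking haplotype. In the window 1 gene differed at least 2-fold, the interferon-induced peptide transporter gene Tap1, at -0.98 and -1.43. Effects on single genes of the segment stay open.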
